A study of Mus musculus with 6 samples.

How the data were processed

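Small RNA libraries were made from the liver of 12-week-old C57BL/6N mice, 3 females and 3 males, that ate a standard chow diet. The labels describe the animals as littermates in normal health, so each library was taken as a separate animal; which animals came from the same litter is not given in the sources used here. Liver pieces were stored frozen in an RNA-stabilising buffer and the libraries were made with a Qiagen miRNA kit, per the labels' protocols. Samples were grouped by the sex stated in their labels, and replicates were numbered in accession order, so the numbers pair no animals.

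The table deposited by the authors holds estimated counts of reads per mature miRNA, which are not normalised. Partek, Bowtie and the mm10 build of the mouse genome are named in the submitters' processing notes, without versions or settings. Trimming, the handling of reads that match several miRNAs, and whether molecular identifiers were collapsed are not given in the sources used here. Of the deposited counts, 98.9% were whole numbers with no tolerance. The 8 largest values were written with 3 digits, which gives them an error of at most 0.45%. Such a table gives relative levels: a miRNA that takes a large share of the reads lowers the share of the others, and reads of near-identical miRNAs can be split between them.

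The table had 2045 rows for 1907 distinct miRNAs; 138 rows repeated another row exactly and were left out. All 1907 positions lay inside an annotated miRNA hairpin on the same strand in the GENCODE M21 annotation of the same build, once the stop column was read as the base after the end. A mature miRNA made from several loci has 1 position in the table. Sequences were read from the genome at these positions. Counts were rounded to whole numbers, which moved at most 0.655% of the total of any tested miRNA.

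Total counts ranged from 3285249 to 16444674 per library, so that 1 count stood for between 0.0635 and 0.285 CPM (counts scaled to a library of 1000000). Intervals on summed counts are exact binomial intervals at 95% and cover counting error only, since reads copied by PCR are not independent molecules. No library pair was a duplicate: the chi-square value per degree of freedom was at least 29.6 for every pair.

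Female and male libraries were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalisation, the filterByExpr filter by group (a minimum count of 10 and a minimum total of 15) and the robust option. The 6 libraries formed 2 groups with no covariate, because the labels give no batch. The numbers in the sample titles run through the males and then the females. Any effect tied to that order cannot be told apart from sex. P-values were adjusted by the Benjamini-Hochberg method over the 370 tested miRNAs, with a threshold of 0.05, and the 370 miRNAs held 99.97% of the counts of each library. Log2 fold changes are female over male. CPM values use TMM-adjusted library sizes. In a single simulated table with 200 of the detected miRNAs changed, the same test recovered 22 of the 26 tested miRNAs with 2-fold changes. It also recovered 25 of 25 with 4-fold changes, and 5 of the 325 unchanged miRNAs were called. Beside the 22 and 25 true calls, these 5 made a larger share of the calls than the threshold of 0.05 aims at.

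Before the data were examined, 20 lists of miRNAs, the test, the alternatives and a naming rule were fixed. The comparison of miR-34a-5p was fixed then too, because the study of SAB, the protein of Sh3bp5, is known for this miRNA. Its choice was therefore not blind to what is known of the study. The lists were the miR-34 and miR-449 family; other miRNAs induced by p53; miRNAs that depend on the growth hormone pattern; miRNAs that target the estrogen receptor; lipid miRNAs; inflammation miRNAs; the miR-29, let-7 and miR-17~92 families; the Dlk1-Dio3 and Sfmbt2 clusters; and the X chromosome. Markers of hepatocytes, erythroid cells, leukocytes, endothelium, stroma, biliary epithelium, muscle and pancreas made up the rest. Lists with at least 3 tested members, 15 of the 20, were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), with a preset correlation of 0.01 and adjustment over the 15 lists. In 20 simulated tables the list test called no list when nothing changed, and called the Dlk1-Dio3 list in all 20 when its members were shifted. The simulated shift was close in size to the list's median in the data. Simulated miRNAs were drawn independently of each other. These tables therefore cannot show how often the test calls a list whose members move together. Of the listed names, 1 was absent from the table. The naming rule took the tested members of the miR-34 family, the 10 miRNAs with the smallest adjusted p in each direction, the 10 most abundant miRNAs, and of each list up to 4 members past the threshold or otherwise up to 3 of its most abundant members. Another 5 miRNAs, miR-3969, miR-1957a, miR-202-3p, miR-369-3p and miR-127-3p, and the other members of the X chromosome cluster of miR-741, were named after their values were seen.

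The alternatives were DESeq2 size factors, library totals with no TMM factor, upper-quartile factors, leaving out the most abundant miRNA, the DESeq2 1.42.0 Wald test, limma-voom, no robust option, no filter, a filter of 50 counts in 3 libraries, repeated rows kept, and each library left out in turn. For lists they included an estimated correlation, the fry test, ranks, and members of a single list only. Thinning every library to the smallest total, 3285249 counts, and list tests without the members past the threshold were chosen after seeing the data.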

Results

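The level of mature miRNAs was measured by small RNA sequencing in healthy liver of 12-week-old C57BL/6N mice, 3 females and 3 males. The study concerns SAB, a mitochondrial outer membrane protein encoded by Sh3bp5, and acute liver injury that depends on sex. The comparison asks which miRNAs differ between the sexes in liver before any injury. Female libraries held 5756418, 3506853 and 3285249 counts, and male libraries 6426337, 4617647 and 16444674, a mean of 4182840 ± 1367256 against 9162886 ± 6370727 (SD, n = 3 each). Between 838 and 1296 miRNAs had a count above 0 in a library, and 313 of the 1907 had none in any. The liver-specific miR-122-5p took 33.2 ± 0.64% of the counts in females and 34.6 ± 0.875% in males. The first principal component of the log2 CPM values, with 51.3% of the variance, separated the sexes, and male replicate 2 lay farthest out along it.

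Female liver held more miR-34a-5p, a p53-induced miRNA, than male liver: 332 ± 18.1 CPM in females against 96.8 ± 25.5 CPM in males (SD, n = 3 each), a 3.43-fold difference. Its log2 fold change was 1.78 (SE 0.20; adjusted p = 0.00016, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Each female library lay above each male library, at 332, 315 and 351 CPM against 126, 77.7 and 86.9 CPM. An exact two-sided permutation test gave p = 0.1, the smallest that 3 animals against 3 allow. The miRNA, TGGCAGTGTCTTAGCTGGTTGT, lies on chromosome 4 from 150068473 to 150068494 (mm10, plus strand) in the Mir34a hairpin, with no other annotated gene on that strand. The only other tested member of the miR-34 and miR-449 family, miR-34c-5p, which shares its seed, stood at 5.61 ± 1.11 CPM in females and 7.64 ± 3.28 CPM in males (SD, n = 3; log2 fold change -0.42, adjusted p = 0.618). Of this family's 2 tested members, 1 was higher over all tested miRNAs, and 1 when adjusted over the list alone.

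Altogether 25 of the 370 tested miRNAs passed the threshold, 12 higher and 13 lower in females. Both arms of the miR-802 hairpin, which is enriched in hepatocytes, were among the largest increases: miR-802-5p reached 503 ± 95.9 CPM in females against 103 ± 30.9 in males (4.88-fold), and miR-802-3p 88.0 ± 13.0 against 19.4 ± 3.23 CPM (4.53-fold). Both had an adjusted p of 0.000106 in edgeR. The hairpin lies on chromosome 16, where miR-802-5p spans 93369737 to 93369758 with no other annotated gene on the plus strand. In the opposite direction, miR-1948-3p, from an intron of Ttc39c on chromosome 18 (12714862 to 12714883), stood at 3.94 ± 0.945 CPM in females against 17.2 ± 1.81 in males (4.46-fold lower, adjusted p = 0.000288, edgeR). The injury- and fibrosis-linked miR-21a-5p, the second most abundant miRNA, was 1.51-fold lower in females (log2 fold change -0.60, SE 0.09, adjusted p = 0.00169, edgeR). Its mature sequence lies within an exon of Vmp1 on chromosome 11 (86584120 to 86584141).

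**Figure D1:**
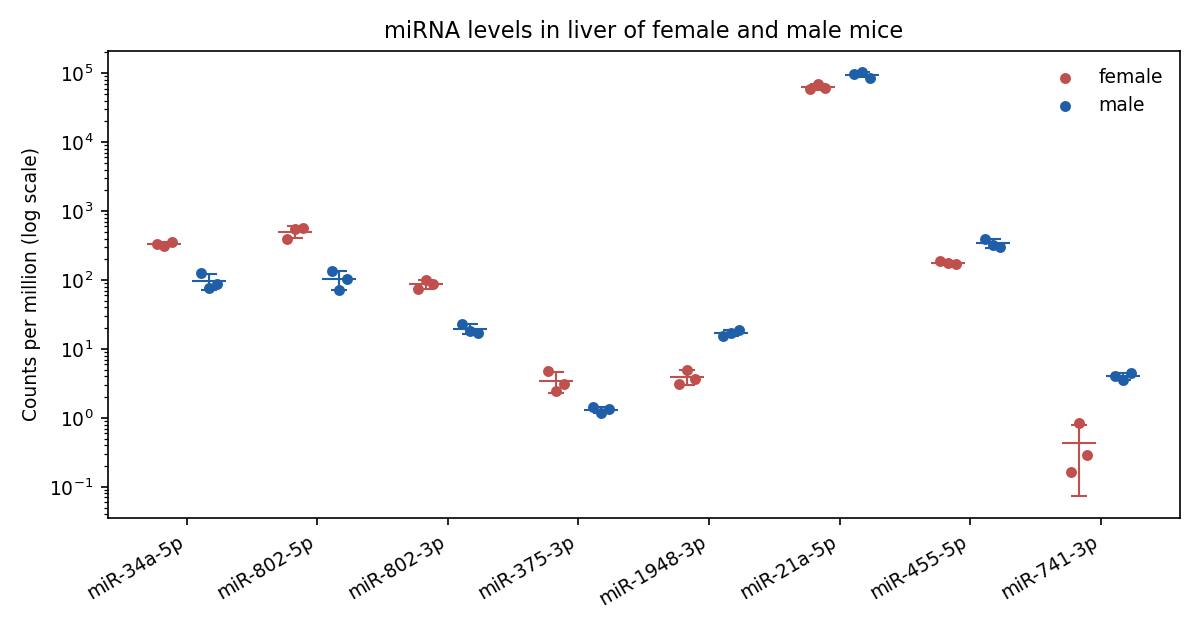
CPM (log scale) of 8 miRNAs in 3 female and 3 male livers; points are libraries, and the horizontal and error bars are the mean ± SD. miR-34a-5p, both miR-802 arms and miR-375-3p were higher in every female library than in any male library, and miR-1948-3p, miR-21a-5p, miR-455-5p and miR-741-3p were lower.

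Among the other increases in females, log2 fold changes were 2.27 for miR-7081-5p, 1.43 for miR-375-3p, an islet miRNA, 0.75 for miR-137-3p and 0.73 for miR-146b-5p, a miRNA linked to inflammation. The level of miR-7081-5p was only 2.69 ± 0.553 CPM in females against 0.59 ± 0.322 in males (SD, n = 3), and that of miR-375-3p 3.47 ± 1.19 against 1.31 ± 0.123. Neither miR-375-3p nor miR-146b-5p passed when any library was left out. Among the decreases, both arms of miR-455, from an intron of Col27a1 on chromosome 4, fell, with log2 fold changes of -0.93 for miR-455-5p and -1.02 for miR-455-3p. Log2 fold changes were -0.68 for miR-339-5p, -1.17 for miR-1903, -1.81 for miR-7021-5p, -0.62 for miR-6390 and -0.80 for miR-21b; the last is uncertain, because its sequence is close to that of miR-21a-5p and reads could be shared. The remaining 3 decreases, named after their values were seen, were miR-3969, miR-1957a and miR-202-3p, at -1.44, -0.81 and -0.95. All 25 had groups that did not overlap, as did 21.6% of the 370 tested miRNAs, where chance gives 10%. The count of calls fell to 9 without female replicate 2, 10 without female replicate 3 and 12 without male replicate 3, and 7 miRNAs passed whichever library was left out: miR-34a-5p, both miR-802 arms, miR-1948-3p, miR-21a-5p, miR-455-5p and miR-741-3p. The balance of directions depended on scaling: 48% of calls were higher in females with TMM, 65% (13 of 20) with no TMM factor and 26.9% (7 of 26) with upper-quartile factors, which moved the median log2 change of all tested miRNAs from -0.01 to 0.13 and -0.10.

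The imprinted Dlk1-Dio3 cluster, a long array of miRNAs on chromosome 12 that is expressed from the maternal allele, had mostly positive log2 fold changes, although 21 of its 25 tested members did not pass the threshold. Of the 25 tested members, between 109585818 and 109743486, 23 had a positive log2 fold change and the median was 0.86. The members past the threshold were miR-541-5p (log2 fold change 0.99), miR-136-3p (1.03), miR-411-5p (0.86) and miR-431-5p (0.98), 4 higher and 0 lower; adjusted over the list alone, 18 were higher and 1 lower. With upper-quartile factors 1 of the 4, miR-541-5p, passed, and none of the 4 passed without female replicate 2 (adjusted p from 0.116 to 0.21, edgeR) or without female replicate 3 (0.0938 to 0.239). In limma-voom miR-136-3p did not pass (adjusted p = 0.0553), while miR-541-5p passed in all 11 other fits on all libraries. The other 2 members, miR-369-3p and miR-127-3p, had log2 fold changes of -0.91 and -0.24, with miR-369-3p at 2354 CPM in male replicate 2 and 696 to 882 CPM elsewhere. Without male replicate 2, miR-127-3p stood at 0.17. The list passed camera with the preset correlation (adjusted p = 1.47e-09), but not with an estimated correlation (adjusted p = 0.533) or in fry (adjusted p = 0.126). Relative to the male mean, the median member stood at 0.29, 1.15 and 1.08 log2 units in female replicates 1, 2 and 3 and at 0.13, -0.23 and 0.08 in the male replicates.

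**Figure D2:**
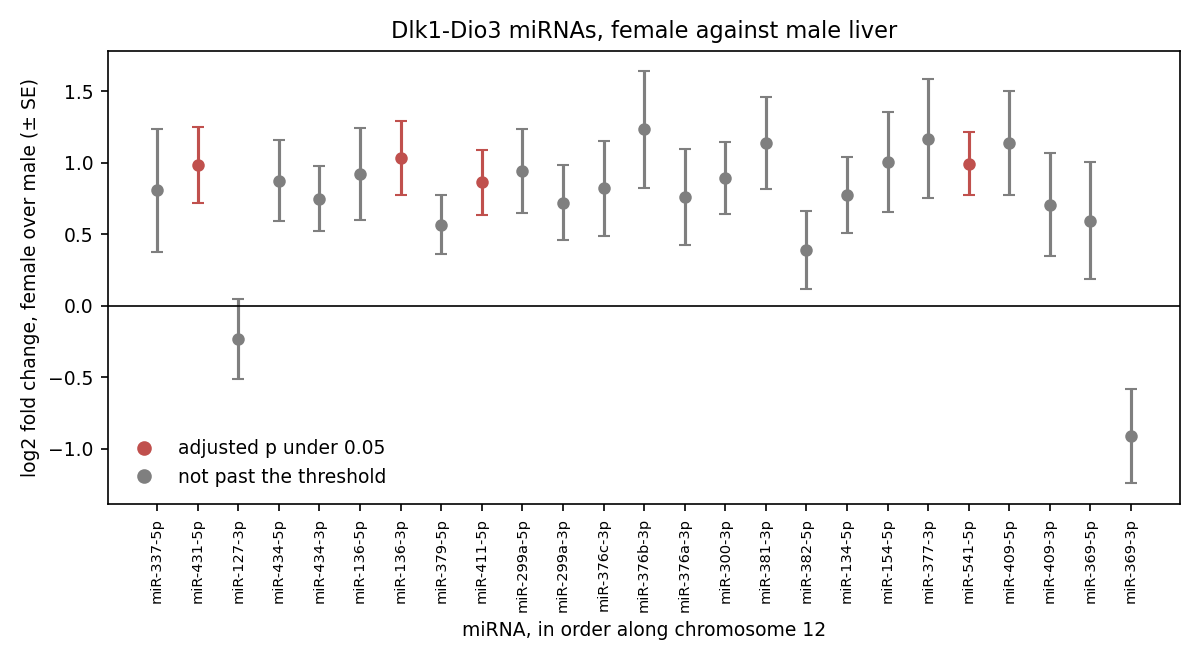
Log2 fold change, female over male, of the 25 tested Dlk1-Dio3 miRNAs in their order along chromosome 12; points are edgeR estimates from 3 libraries per sex and bars are ± SE. Red marks the 4 miRNAs with an adjusted p under 0.05; 23 of the 25 lie above 0, and miR-127-3p and miR-369-3p lie below.

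Of the marker lists for other liver cells, leukocyte and stromal markers passed camera with the preset correlation, in opposite directions. Neither passed in fry for a shared direction (adjusted p = 0.11 each). In fry for changes in either direction, adjusted p was 0.0277 for leukocyte and 0.0204 for stromal markers. All 8 leukocyte markers had positive log2 fold changes, with a median of 0.29 (camera adjusted p = 0.0396; adjusted p = 0.533 with an estimated correlation), and 1 was higher, the myeloid miR-223-3p at 0.62, also when adjusted over the list alone. Its adjusted p in edgeR was 0.107 with upper-quartile factors, 0.14 without female replicate 2, 0.273 without female replicate 3 and 0.133 without male replicate 3. In limma-voom the adjusted p of miR-223-3p was 0.0553. All 10 stromal markers had negative values, with a median of -0.27 (camera adjusted p = 0.0293; adjusted p = 0.533 with an estimated correlation). None of the stromal markers passed, over all tested miRNAs or adjusted over the list alone; miR-143-3p stood at -0.21, miR-199a-3p at -0.38 and miR-199b-3p at -0.35, and the last 2 have the same mature sequence. With upper-quartile factors miR-199a-3p passed, at -0.48 (adjusted p = 0.0462, edgeR). With upper-quartile factors the leukocyte list had an adjusted p of 0.062, and the stromal list had 0.0811 with no filter and 0.0681 with the filter of 50 counts. With members of a single list only, adjusted p was 0.14 for the leukocyte and 0.0555 for the stromal list, and without miR-223-3p the leukocyte list had 0.136. Leaving out female replicate 1, female replicate 3 or male replicate 3 ended both calls; without male replicate 2 the leukocyte list had 0.0766, and without male replicate 1 the stromal list had 0.196. Over the camera fits with the preset correlation, adjusted p ranged from 0.0118 to 0.227 for leukocyte and from 0.00659 to 0.196 for stromal markers.

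The hepatocyte list, with 7 of 9 members positive and a median of 0.16, had an adjusted p of 0.0509 in camera, which ranged from 0.0116 with no filter to 0.679 without its members past the threshold; these were both miR-802 arms, and 2 were higher and 1 lower when adjusted over the list alone. The 5 erythroid markers had a median of 0.13 (camera adjusted p = 0.59), with miR-144-3p at 0.23, miR-144-5p at 0.13 and miR-486a-5p at 0.03. The 6 biliary and epithelial markers had a median of -0.22 (camera adjusted p = 0.254), with miR-200a-3p at -0.22, miR-200b-3p at -0.26 and miR-31-5p at -0.14. None of the erythroid or biliary markers passed, also when adjusted over the list alone. The lists with under 3 tested members had no set test: the 2 endothelial markers were miR-126a-3p at -0.07 and miR-126a-5p at 0.02, the 2 muscle markers miR-1a-3p at 0.06 and miR-206-3p at 0.52, and the only pancreas marker miR-375-3p. Of these, miR-375-3p passed, over all tested miRNAs and adjusted over the list alone.

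Of the 3 tested miRNAs known to depend on the growth hormone pattern, both miR-802 arms were higher and miR-1948-3p lower, also when adjusted over the list alone (camera adjusted p = 0.254). Camera tests for a shared direction, so opposite signs within this list weaken its result. In fry for changes in either direction, its adjusted p was 0.0199, although 2 of the 3 members are arms of the same hairpin. The inflammation list held higher miR-146b-5p and miR-223-3p and lower miR-21a-5p, 3 of 10 tested members, and 5 passed when adjusted over the list alone, 2 higher and 3 lower (median 0.01, camera adjusted p = 0.896). With upper-quartile factors both higher calls of this list were lost, leaving 0 higher and 2 lower. Of 16 tested lipid miRNAs, miR-34a-5p and miR-223-3p were higher; 2 were higher and 1 lower when adjusted over the list alone (median 0.05, camera adjusted p = 0.46). None passed, also when adjusted over the list alone, among 10 other p53-induced miRNAs (median -0.02, camera adjusted p = 0.896), 10 that target the estrogen receptor (0.08, 0.479), 5 of the miR-29 family (0.01, 0.896), 10 of the let-7 family (-0.10, 0.336) and 14 of the miR-17~92 family (0.14, 0.46). The median changed sign with no TMM factor for p53-induced and let-7 miRNAs, and with upper-quartile factors for inflammation, lipid, estrogen receptor and miR-29 miRNAs. With upper-quartile factors let-7c-5p passed, at -0.30 (adjusted p = 0.0462, edgeR). In these lists the log2 fold changes were 0.17 for miR-194-5p, 0.14 for miR-22-3p, -0.03 for miR-26b-5p, -0.09 for miR-29b-3p, -0.0037 for miR-29c-3p, -0.21 for let-7c-5p, 0.16 for miR-93-5p, -0.08 for miR-25-3p and -0.08 for miR-19b-3p. The Sfmbt2 cluster had 2 tested members, miR-467e-5p at 0.67 and miR-669c-5p at 0.33, neither past the threshold over all tested miRNAs or adjusted over the list alone.

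Most of the abundant liver miRNAs lay close between the sexes. The 10 most abundant held 73.4 to 76.8% of the counts of a library, and of these miR-21a-5p passed the threshold. The log2 fold change of miR-122-5p was -0.21 (adjusted p = 0.053, edgeR), and its adjusted p ranged from 0.00763 with upper-quartile factors to 0.46 in the DESeq2 Wald test. The other 8 were let-7f-5p at -0.14, miR-16-5p at 0.08, miR-126a-3p at -0.07, miR-192-5p at 0.02, miR-29a-3p at 0.01, miR-26a-5p at -0.09, let-7a-5p at -0.11 and miR-148a-3p at -0.18.

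Of 33 tested miRNAs encoded on the X chromosome, 1 was higher in females (miR-223-3p) and 1 lower (miR-741-3p), also when adjusted over the list alone (median 0.03, -0.06 with upper-quartile factors; camera adjusted p = 0.451). Low counts of miR-741-3p (chromosome X, 66796809 to 66796831, minus strand) were seen in males, 26, 15 and 70, and 1, 3 and 1 in females, with an adjusted p of 0.00164 in edgeR. Its summed counts over summed TMM-adjusted library sizes gave a male to female ratio of 11.1 (95% exact counting interval 4.63 to 34.9). Its neighbours, singled out after their values were seen, were too low to be tested singly. The cluster holds 34 mature miRNAs between 66776760 and 66839121, all on the minus strand. Without miR-741-3p they summed to 41, 48 and 118 counts in the male libraries and 8, 6 and 4 in the female libraries, 8.44 ± 2.56 against 1.37 ± 0.264 CPM (SD, n = 3 each). From the counts summed over each sex and divided by the summed TMM-adjusted library sizes, the male to female ratio was 5.76 (95% interval 3.56 to 9.92). Of the 24 members seen in any library, 14 had counts in males and none in females, miR-743a-3p and miR-871-3p among them, and 1 had counts in females and none in males. Before TMM adjustment, male libraries held 27488657 counts in sum and female libraries 12548520; after thinning to equal totals, 20 members were seen, 12 of them in males alone and 2 in females alone.

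**Figure D3:**
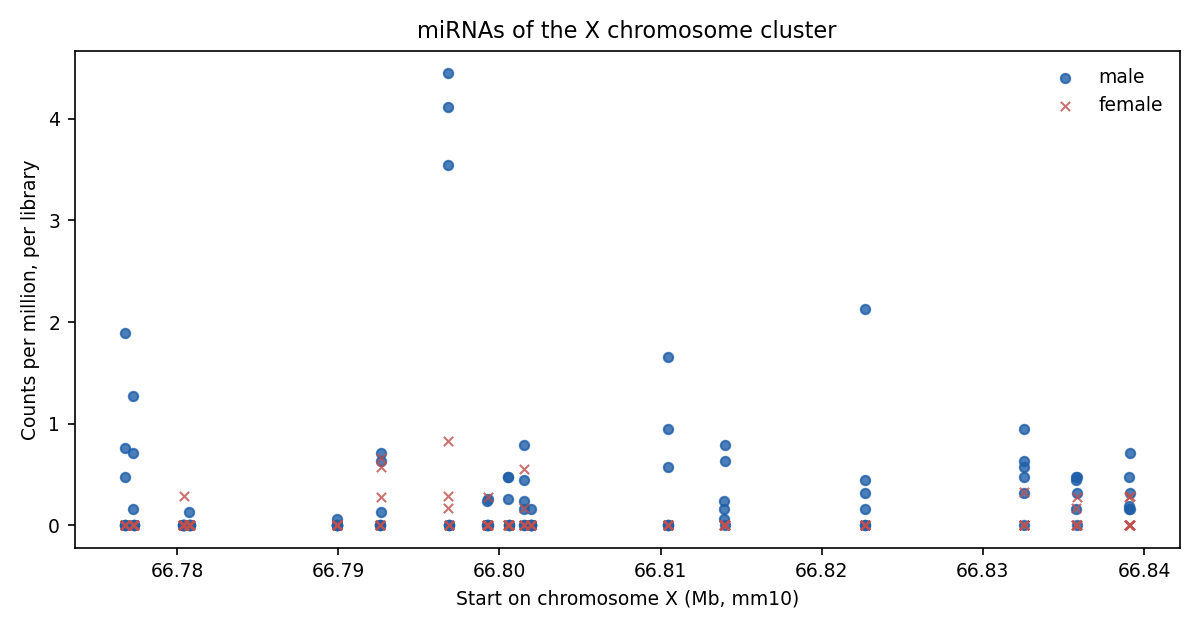
CPM of each mature miRNA of the cluster, by its start on chromosome X in Mb; each symbol is a library, circles for 3 males and crosses for 3 females. The highest points are miR-741-3p, with a mean of 4.04 CPM in males and 0.427 CPM in females.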

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

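Thinning to equal depth and the list test without members past the threshold were chosen after seeing the data. The log2 fold change of miR-34a-5p kept its side of the threshold in all 17 other fits, from 1.65 to 1.99. The count of 25 miRNAs stayed within 1.5 times in the planned fits on all libraries, at 20 with no TMM factor to 31 in DESeq2; it was 16 after thinning, where fewer counts were left, and 9 to 32 when a library was left out. In all 17 fits, 6 of the 25 were kept. The 3 lists became 0 with an estimated correlation, 0 in fry for a shared direction and 1 with members of a single list only, and 1 to 3 without a library. At an unadjusted fry p under 0.05 for a shared direction there were 5 lists. For changes in either direction, fry called 7 lists after adjustment. They were the hepatocyte, growth hormone, lipid, inflammation, X chromosome, leukocyte and stromal lists. The Dlk1-Dio3 list was not among them (adjusted p = 0.0753, fry). It was called in every camera fit with the preset correlation. The runs with the preset and the estimated correlation differed in that setting only, and the cause of the other changes was not tested. The DESeq2 Wald test and the fit without the robust option do not enter the list test, and a pseudocount alternative did not apply to counts. Of the 986 values of 59 named miRNAs, 823 kept direction and side, 102 lost and 8 gained the threshold, and 53 changed sign. A change of scaling shifts all values nearly alike. With no TMM factor the median log2 change of all tested miRNAs moved from -0.01 to 0.13. With upper-quartile factors it moved to -0.10. Such shifts carry values near 0 across it. For the other fits the cause of the sign changes was not tested. All that changed sign were miRNAs not past the threshold. With no TMM factor these were let-7a-5p 0.030, let-7f-5p 0.0082, miR-126a-3p 0.072, miR-19b-3p 0.048, miR-25-3p 0.059, miR-26a-5p 0.048, miR-26b-5p 0.11, miR-29b-3p 0.045, miR-29c-3p 0.13 and miR-31-5p 0.0087. With upper-quartile factors they were miR-126a-5p -0.080, miR-16-5p -0.013, miR-192-5p -0.075, miR-1a-3p -0.052, miR-29a-3p -0.083 and miR-486a-5p -0.063. Without miR-122-5p they were miR-126a-5p -0.013, miR-192-5p -0.016, miR-29a-3p -0.022 and miR-486a-5p -0.0017. With the filter of 50 counts they were -0.014, -0.015, -0.022 and -0.0027 in the same order. With repeated rows kept, miR-29c-3p stood at 0.013, and after thinning at 0.0056, with miR-1a-3p at -0.15. Without a library, ranges were -0.057 to 0.094 for miR-126a-5p, -0.14 to 0.53 for miR-144-3p, -0.27 to 0.33 for miR-144-5p, -0.30 to 0.0048 for miR-148a-3p, -0.039 to 0.040 for miR-192-5p, -0.31 to 0.16 for miR-19b-3p, -0.21 to 0.33 for miR-1a-3p, -0.082 to 0.038 for miR-26b-5p, -0.032 to 0.055 for miR-29a-3p, -0.087 to 0.037 for miR-29c-3p, -0.14 to 0.41 for miR-486a-5p and -0.43 to 0.17 for miR-127-3p. Depth limits the low miRNAs: 1 count was worth 0.285 CPM in female replicate 3.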

Other observations

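The tests for stromal cells, testis reads and depth of the X chromosome cluster below were chosen after the results were seen. The arms of a hairpin tended to change together. Among the 6 hairpins with an arm past the threshold and both arms tested, both arms had the same sign in all 6, and both passed in 2, miR-802 and miR-455. For miR-223 the sign was shared but not the size: miR-223-5p stood at 0.07 (adjusted p = 0.942, edgeR) and miR-223-3p at 0.62. Across the 92 hairpins with both arms tested, the log2 fold changes of the 5p and 3p arms correlated with Pearson's r = 0.672 and Spearman's rho = 0.48 (permutation p = 1e-05 for each, the smallest that the random pairings drawn can give). Among the 86 hairpins with no arm past the threshold, r was 0.424 (permutation p = 0.00011). The values are across hairpins, which are not independent replicates, and are consistent with a difference in the amount of precursor between the libraries of the sexes; sex itself and other differences between the libraries remain open.

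Sh3bp5, the gene of SAB, has 2 coding transcripts with a 3′ untranslated region of 1199 nt in the annotation. miR-34a-5p had 0 matches to its 6 or 7 nt seed in either transcript, which leaves other kinds of pairing open. Matches to a 7 nt seed were counted anywhere in the transcripts, of 2684 and 2633 nt, so also outside the 3′ untranslated region. They were found for 2 of the 12 miRNAs higher in females and for 81 of the 358 other tested miRNAs (two-sided Fisher's exact p = 1). The hypothesis that the miRNAs higher in females were enriched for such matches was not borne out: their share was 16.7% against 22.6%. With only 12 miRNAs, a modest enrichment cannot be excluded. Of the 13 lower in females, 4 had such a match, a share of 30.8%.

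The mostly positive log2 fold changes of Dlk1-Dio3 miRNAs may be technical or biological. After all libraries were thinned to equal totals, the list's median log2 fold change was 0.83. Random thinning keeps each miRNA's expected share, so this does not decide whether library differences that go with depth play a part. Female replicates 2 and 3, with the highest medians, had the lowest totals, 3506853 and 3285249 counts. Male replicate 2, next at 4617647 counts, had the lowest median, at -0.23. A single library is argued against as the whole cause, since the lowest median without a library was 0.63, without female replicate 2; female replicate 1 nevertheless lay close to the males. More stromal cells in the female samples are argued against by a median of -0.27 over the 10 stromal markers, all below 0. That list itself did not pass in fry for a shared direction or with an estimated correlation. All 8 leukocyte markers lay above 0, with a median of 0.29, and a difference in leukocytes was not tested as a source. The shared movement of the cluster (estimated correlation 0.574) stays open as the reason for its low p with the preset correlation, and a difference between the sexes stays open as an untested hypothesis.

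For the X chromosome cluster, libraries thinned to equal totals gave a male to female ratio, without miR-741-3p, of 5.33 (95% counting interval 3.05 to 9.97). The ratio before thinning, 5.76, was already divided by library size, and random thinning keeps expected shares. The thinned ratio could hardly differ, so it does not decide whether library differences that go with depth play a part. The bound set before it, a ratio of at least 5 with its whole interval, was not met. The bound used in its place, an interval above 2, was set afterwards and was met. Reads from testis, where miRNAs of this cluster are known to be abundant, could be a source in male libraries only. The 6 testis miRNAs listed for this test, all also counted in female liver, had a male to female ratio of 1.21 (0.943 to 1.55), from summed counts over summed TMM-adjusted library sizes, as for the other ratios without thinning. Of their female counts 77.7% were miR-34c-5p, and without it the ratio was 1.19 (0.704 to 2.09), on 21 female and 50 male counts. Both ratios lie below that of the cluster, but they do not decide about testis reads. These miRNAs are also counted in female liver, and the amount of each that testis reads would bring is not known from these tables. Outside that list, miR-202-3p, a gonadal miRNA, had a ratio of 2.01 (1.51 to 2.72), while the other arm of its hairpin, miR-202-5p, which is in the list, had 3 counts in females and 0 in males. On these low counts a small share of testis reads cannot be told apart from a sex difference within liver.

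With 3 animals per sex there are 10 splits of the libraries, too few for a share under 0.05. The real split, 1 of the 10, called 25 miRNAs and the highest of the others 0. For lists, also 1 of the 10 gave as many, 3 against 2 in the highest of the others. Some of the remaining splits called 1 list although they called no miRNA.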
